A study of Mus musculus with 2 samples.

How the data were processed

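RNA bound to FAM120A, an RNA-binding protein that associates with Argonaute 2, was measured by iCLIP (individual-nucleotide resolution crosslinking and immunoprecipitation) in mouse embryonic stem cells. Per the labels' protocols, both cell lines carried a doxycycline-inducible lentiviral Fam120a gene and received doxycycline at 2.5 µg/mL. In the tagged line the protein carried FLAG and HA epitopes. In the untagged line it did not, so that the library from this line measured what the FLAG and HA immunoprecipitations recovered without the epitopes. Cells were crosslinked with ultraviolet light, the lysate was partly digested with RNase I, and complexes of the expected size were cut from a membrane before library construction. There were 2 samples, with 1 library per group.

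The authors deposited 2 lists of read clusters, 1 per library, each holding clusters enriched over the other library. Per the submitters' processing notes the genome build was mm9. The aligner, the cluster caller and the treatment of PCR duplicates are not given in the sources used here. Each deposited cluster has a position, a strand, a name, a read count at its highest position in most cases, and 3 joined values. The deposited lists have no header, so the meaning of these 3 values was worked out from the values themselves. The first is the read count of the cluster in its own library. The second is a log2 ratio of own to other reads after adding 1 to each. The third is the p-value of a one-sided exact binomial test of own against other reads at an even split. The deposited lists reach down to 5 reads and up to a p of 0.0494. Clusters are named by the authors as region B, C1 or C2 or in the form of a splice junction, and neither the letters nor the fields of the junction names are explained in the sources used here. The count of a cluster can be many times the count at its highest position, and neighbouring clusters can share reads, so counts were not summed over clusters.

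The reads of the other library were recovered by finding, for each cluster, the whole number that gave back both the listed log2 ratio (tolerance 0.006) and the listed p (tolerance 0.0001, or 0.001 in relative terms for smaller p). This gave a whole number for 100% of clusters in both lists. 5 clusters of the tagged list and 9 of the untagged list had several such numbers, of which the one closest to the listed p was taken. On data simulated for the tagged list, with 7246 clusters, 100% of the reads of the other library were recovered. The simulated values were made with the same ratio and test that the recovery inverts. This checks the computation and not the inferred meaning of the listed values, and untagged-list counts were not simulated. At tagged-list clusters the recovered numbers were rounded multiples of 1 factor, between 1.5 and 1.501. The authors' values therefore compare own reads with reads of the other library scaled by a factor. That this scaling brings the libraries to the same depth is inferred, and the factor is called the depth factor on that reading. Values up to 60 alone allowed factors up to 1.512, and the range was narrowed after this was seen by requiring that every value with 1 candidate be such a multiple, so that all values fit the final factor by construction. A fit on every second cluster, tested on the rest over values of 1 to 60, was therefore added. The midpoint, 1.501 after rounding, was used. This factor is the only measure of relative depth here, and the total depth of the libraries is unknown. Counts of the other library are printed after this scaling unless called unscaled.

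Clusters on 1 strand separated by at most 1000 nt were merged into loci. Spacing was compared with 100 draws of uniform positions between the outermost clusters of each chromosome, with strands and lengths kept. Strand agreement of neighbouring clusters was compared with 100 shuffles of the strands. Merging was tested on simulated data, where 300 of 300 planted loci were found. The planted loci lay far apart, so this checks the computation and not the choice of 1000 nt. For clusters of at least 20 reads, reads were called spread when at most 50% of them lay at the highest position and stacked when over 75% did. Intervals on shares are Wilson 95% intervals, intervals on medians are from binomial order statistics, and intervals on read ratios are exact binomial (Clopper-Pearson) intervals after division by the depth factor. They cover counting error only, since reads are not known to be independent molecules and clusters of a locus are not independent. With 1 library per group the difference between the libraries has no replicate check, and no test between the groups was made.

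Before the data were examined, the loci to be named were fixed: in each list, those with the most clusters and those holding the cluster with the lowest listed p, 10 per rule for the tagged list and 5 for a list of under 2000 clusters. Ties were broken by the summed listed count at the highest positions. The gene-based parts of the plan (genomic features, genes, gene lists, sequence at clusters and miRNA seed matches) were not run: the gene table used here is on GRCm38, the clusters are on mm9, no genome sequence was used, and coordinates were not converted between builds. Loci are therefore named by mm9 position, counted from 1, without a gene or feature. The alternatives were the 50% of each list with the lower p (ties kept), merging within 50 or 10000 nt, leaving out chrM, other rules of overlap and a length limit. A binomial test on unscaled reads with the depth factor as the expected odds (the depth-aware test), leaving out class B, leaving out junctions, shares with 0 other reads at 20 or more reads, and all settings for strand agreement and for spread reads were added after seeing the data. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.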

Results

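The series asked which RNA positions FAM120A contacts in mouse embryonic stem cells, using crosslinking and immunoprecipitation of an epitope-tagged protein with the untagged protein as background. It held 1 tagged and 1 untagged library, each given as a list of the read clusters enriched over the other library. The tagged list had 11670 clusters and the untagged list 1134. Clusters held a median of 8 reads in the tagged list (95% interval 8 to 9) and 24 in the untagged list (21 to 27), with maxima of 4343 and 10600. Most clusters were 26 nt long, 79.5% in the tagged list and 96.8% in the untagged list.

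The untagged library had 0 reads at 8153 tagged-list clusters, or 69.9% (69 to 70.7), a share set largely by the listing rule. No tagged-list cluster of 8 or fewer reads had reads in the untagged library, and 50.4% of the list was of this size. Among tagged-list clusters of 20 or more reads the share with 0 untagged reads was 16.1% (14.6 to 17.8). The tagged library had 0 reads at 141 untagged-list clusters, or 12.4% (10.6 to 14.5), and at 0.315% (0.0863 to 1.14) of those with 20 or more reads. The median listed log2 ratio of own to other reads was 2.81 in the tagged list and 1.37 (1.3 to 1.44) in the untagged list. Against 0 reads this ratio is set by the cluster's own reads and the added 1, so the tagged-list median is not a measured fold. A log2 ratio of at least 3 was listed for 4511 clusters of the tagged list (38.7%) and for 56 of the untagged list (4.94%), and a ratio under 1 for 372 (3.19%) and 389 (34.3%). Of the tagged-list clusters, 2714 (23.3%) held 5 reads against 0, the lowest count listed, and 8634 (74%, interval 73.2 to 74.8) stayed under a p of 0.05 in an exact one-sided binomial test that used unscaled reads and the depth factor. That test compares these 2 libraries, not the conditions. These shares describe 2 lists that were each selected for enrichment, so part of the difference between them follows from how many reads each cluster held.

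**Figure D1:**
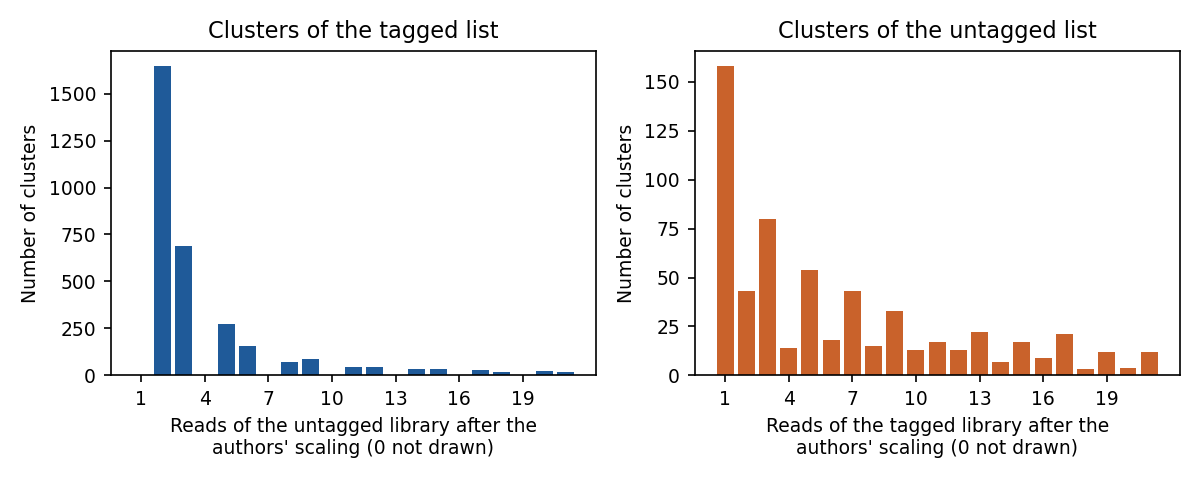
Number of clusters (y axis) by the reads of the other library after the authors' scaling (x axis, 1 to 21 reads), for the tagged list (left, untagged reads) and the untagged list (right, tagged reads). At tagged-list clusters no cluster has 1, 4 or 7 reads, whereas 1646 have 2 and 691 have 3.

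Tagged-list clusters were concentrated in loci on 1 strand. The 11670 clusters fell into 4724 loci, of which 226 held at least 10 clusters each and together 3646 clusters (31.2%). Many clusters lay almost end to end. Merging those within 50 nt left 7902 clusters in the tagged list, and 1107 of 1134 in the untagged list. Whether clusters this close are separate sites or pieces of 1 stretch of reads is not known. The locus with the most clusters lay on chromosome 11, minus strand, positions 95818562 to 95824773, with 56 clusters over 6212 nt and a median log2 ratio of 2.78. Its cluster with the lowest p had 266 tagged reads against 5 unscaled untagged reads, a depth-adjusted ratio of 35.4 (15 to 110.1). The next locus lay on chromosome 19, minus strand, positions 5796050 to 5802393, with 49 clusters and a median log2 ratio of 2.58, and the locus after it on chromosome 1, plus strand, positions 133827830 to 133832733, with 48 clusters and a median of 3.17. The untagged library had 0 reads at 33 of these 48, so the median of 3.17 is not a measured fold. On chromosome 19, plus strand, positions 44377789 to 44380845 held 40 clusters with a median of 3. The plus strand of chromosome 11 held 37 clusters at positions 87863102 to 87865144, with a median of 3.21, and the minus strand of chromosome 5 held 37 at positions 92481194 to 92483780, with a median of 2.81. The plus strand of chromosome 16 held 36 at positions 44159767 to 44162358, with the highest median of these 10 loci, 3.54. At 21 of these 36 the untagged library had 0 reads, so this median is not a measured fold. The cluster with the lowest p in this locus had 38 tagged reads against 0. That is a depth-adjusted ratio of at least 8.44-fold against a floor of 3 unscaled untagged reads, while its exact 95% interval began lower, at 6.54. Positions 72595120 to 72597618 on the plus strand of chromosome 9 held 35 clusters (median 2.74), and positions 136384374 to 136386864 on the minus strand of chromosome 5 held 34 (median 3.12).

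The mitochondrial locus had the lowest median ratio of these 10. On the plus strand of chrM, positions 334 to 6354 held 34 tagged-list clusters with a median log2 ratio of 1.26, ranging from 0.24 to 3.81. Its cluster with the lowest p, at positions 457 to 482, had 369 tagged reads against 149 unscaled untagged reads, a depth-adjusted ratio of 1.65 (1.36 to 2.01). In all, chrM held 55 tagged-list clusters, 49 of them on the plus strand, and 5 untagged-list clusters.

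The 10 loci holding the clusters with the lowest listed p were partly other loci. The lowest p, 1.34e-302 in the authors' one-sided exact binomial test, was on chromosome 5, minus strand, positions 143664948 to 143664973, with 1368 tagged reads against 54 unscaled untagged reads, a depth-adjusted ratio of 16.9 (12.9 to 22.6). Its locus, positions 143664829 to 143665608, held 13 clusters in 780 nt, and the untagged library had reads at each of them. On chromosome 5, plus strand, positions 130320895 to 130322171 held 9 clusters, and the cluster with the lowest p had 995 tagged reads, 10.4 times the untagged level (8.04 to 13.6). On chromosome 11, minus strand, positions 69730365 to 69730839 held 9 clusters, and its leading cluster had 671 reads, 27.9 times the untagged level (17.1 to 49.2). On chromosome 18, minus strand, positions 35062611 to 35065752 held 31 clusters, with a leading cluster of 375 reads at 27.8 times the untagged level (14.5 to 61.2). The loci on chromosome 11 from 87863102 and from 95818562 and on chromosome 5 from 136384374 were named by both rules. In the last, the cluster with the lowest p had a ratio of 58.2 (19.7 to 284). On chromosome 9, plus strand, positions 44445602 to 44448613 held 31 clusters (leading cluster 224 reads, ratio 24.9, interval 11.3 to 68.5). On chromosome 12, plus strand, positions 87860036 to 87862493 held 30 (leading cluster 205 reads, ratio 22.8, interval 10.3 to 62.8). The remaining member of the 10 was a single cluster on chromosome 6, plus strand, positions 69246620 to 69246645, with 214 reads, of which 99.1% lay at 1 position, and a ratio of 20.4 (9.72 to 51.3).

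**Figure D2:**
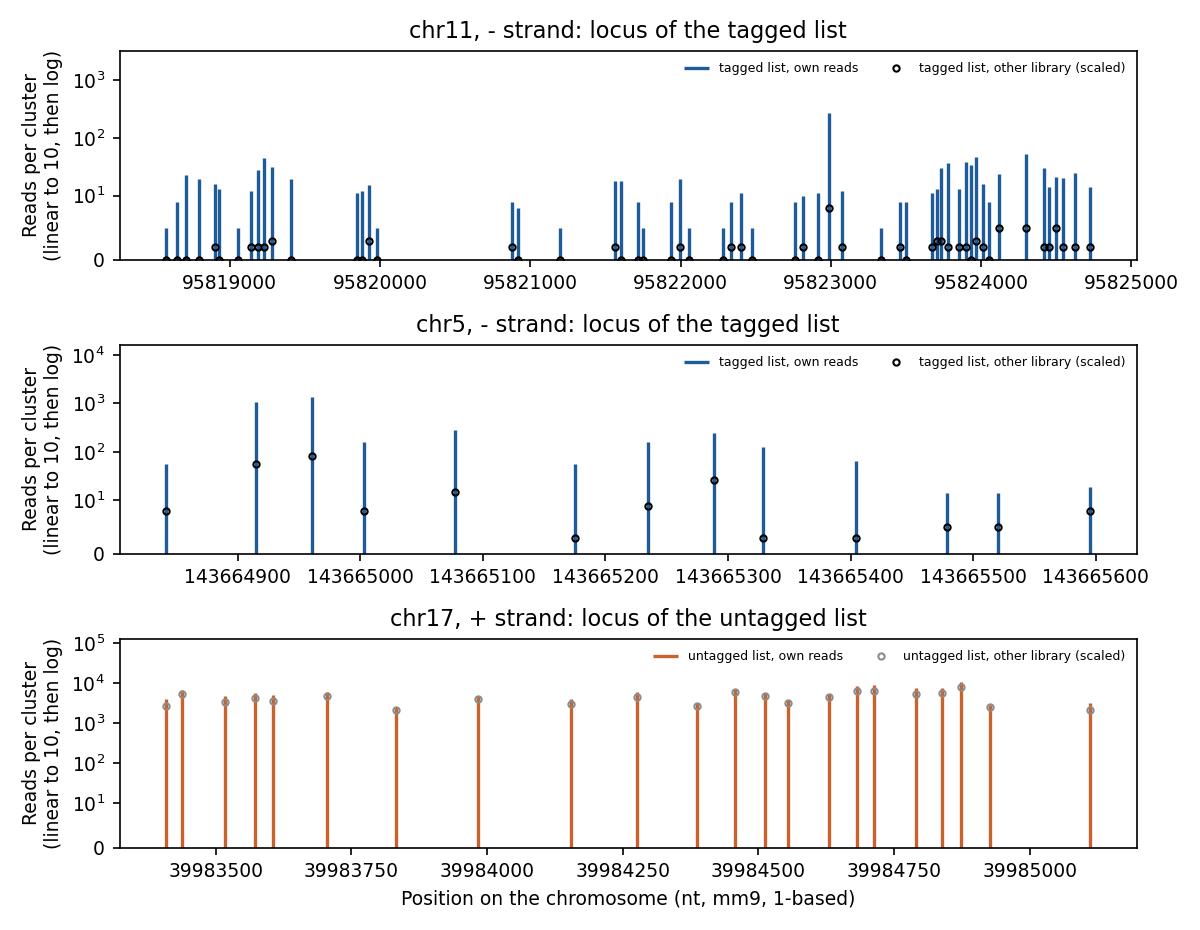
Reads per cluster (y axis, linear to 10 and logarithmic above) against mm9 position (x axis) for the locus with the most tagged-list clusters (top, 56 clusters), the locus with the lowest listed p (middle, 13 clusters) and the locus with the most untagged-list clusters (bottom, 22 clusters). Lines are reads of the listed library and circles the scaled reads of the other library; the circles lie below the line ends in the top and middle maps and close to them in the bottom map.

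Most of the untagged-list loci named by the 2 rules had small differences between the libraries, unlike the untagged list as a whole, where 34.3% of clusters had a log2 ratio under 1. The one with the most clusters, on chromosome 17, plus strand, positions 39983396 to 39985124, held 22 clusters with log2 ratios of untagged to tagged reads between 0.14 and 0.6. Its cluster with the lowest p had 9076 untagged reads against 6257 scaled tagged reads. On chrM, plus strand, positions 2029 to 2667 held 5 untagged-list clusters with a median log2 ratio of 0.47. On chromosome 14, minus strand, positions 51427173 to 51427427 held 4 clusters with a median of 0.6. On the plus strand, positions 3150837 to 3151523 of chromosome 6 and 61962991 to 61963254 of chromosome 3 held 3 clusters each, with medians of 0.56 and 0.48. Of the 5 loci holding the clusters with the lowest p, 2 were these loci on chromosomes 17 and 6. The clusters on chromosome 18, plus strand, positions 68851753 to 68851778, and on chromosome 9, plus strand, positions 123371052 to 123371115, had log2 ratios of 0.66 and 0.41 with 2894 and 4867 untagged reads. The remaining 1, on chromosome 3, minus strand, positions 144057096 to 144057121, had 158 untagged against 31 scaled tagged reads, a log2 ratio of 2.31, with 96.8% of its reads at 1 position.

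The lists differed in how clusters were spaced. In the tagged list 72.1% of clusters (71.2 to 72.9) had another cluster within 1000 nt on the same strand, against 0.958% on average in uniform draws. In the untagged list this share was 5.73% (4.52 to 7.24), against 0.223% in draws, and it was 3.87% without the chromosome 17 locus of 22 clusters. Without class B, which made up more of the untagged list, the shares were 87.6% in the tagged list and 48.7% in the untagged list. The latter rests on few clusters, 109 of them in class C2, and the chromosome 17 locus was not left out of it. The median distance to the nearest cluster was 59 nt in the tagged list and 1218828 nt in the untagged list, which has fewer clusters. In class C2 of the tagged list it was 16 nt, and clusters this close may not be separate sites. Of the untagged-list loci 98.3% were single clusters, against 69% in the tagged list. Neighbouring tagged-list clusters at most 10000 nt apart lay on the same strand in 7270 of 7349 pairs, or 98.9% (98.7 to 99.1), where shuffled strands gave at most 51.6%. Most of these pairs, 6955, lay within 1000 nt, and 6945 of the 6955 shared a strand. The untagged list had 64 pairs within 10000 nt, of which 85.9% (75.4 to 92.4) shared a strand, against at most 65.6% after shuffling. Of the 64, 48 lay within 1000 nt, with 46 on the same strand. Without the chromosome 17 locus of 22 clusters the untagged-list share was 78.6%. The agreement thus rests mostly on close clusters that may be pieces of 1 stretch of reads. Uniform draws do not allow for the share of the genome that is transcribed, so they mark only what no preference for position would give.

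**Figure D3:**
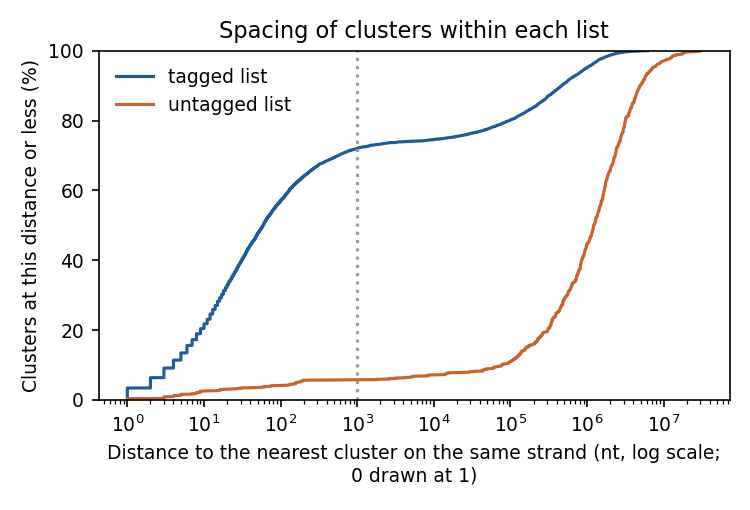
Share of clusters (y axis, percent) with another cluster of the same list and strand at or within a given distance (x axis, nt, log scale); the dotted line marks 1000 nt. At that distance the tagged list has reached 72.1% and the untagged list 5.73%.

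Chromosomes contributed unequally. Chromosomes 11 and 1 held the most tagged-list clusters, 1093 and 1071, in 350 and 361 loci. The number of tagged-list clusters per untagged-list cluster ran from 5.56 on chromosome 17 to 15.1 on chromosome 1 over the chromosomes with clusters of both lists. Counted as loci over the same chromosomes, the ratio ran from 3.17 on chromosome 16 to 6.48 on chromosome 8. On chromosome 17 the loci ratio was 3.84. Chromosome Y held 7 tagged-list clusters in 2 loci and 0 untagged-list clusters. By strand, 49.8% of tagged-list clusters (48.9 to 50.7) and 53.6% of untagged-list clusters (50.7 to 56.5) lay on the plus strand.

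Clusters whose names have the form of a splice junction were mostly in the tagged list, 38 (0.326%) against 1 (0.0882%). The names are read here as the ends of a gap that reads crossed, which is inferred from their form, and whether they count positions from 0 or 1 is unknown. Read so, the 38 carried 34 distinct junctions with gaps of 131 to 16499 nt, a median log2 ratio of 2.81 and 0 untagged reads at 28 of them. Of the 38, 30 lay within 1000 nt of a tagged-list cluster that was not named by a junction. Their median distance to the nearest tagged-list cluster of any name was 0 nt, which means overlap or touch, so reads can be shared with that neighbour. The highest count, 97 tagged reads against 5 unscaled untagged reads, belonged to a junction on chromosome 5, minus strand, from 100390307 to 100391533. On chromosome 1, minus strand, the junction from 88251674 to 88252626 was named by 2 clusters, with 53 and 17 reads. The junction on chromosome 11, minus strand, from 53076456 to 53078535 was likewise named by 2 clusters, with 22 and 9 reads and 0 untagged reads at both. The untagged-list junction, on chromosome 7 from 87525168 to 87525724, had 93 untagged against 67 scaled tagged reads, and the strand fields in its name differed from each other. They also differed in 1 tagged-list junction, on chromosome 6 from 137785895 to 137786176. The junctions described here were chosen after their values were seen.

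In the tagged list, clusters called spread had higher ratios than clusters called stacked. Among the 1995 tagged-list clusters of at least 20 reads, 1126 had spread reads and a median log2 ratio of 3.37 (3.27 to 3.46), and 546 had stacked reads and a median of 1.1 (1.03 to 1.17). The class named region B by the authors held 518 of the 546 stacked clusters. Without it, the stacked median was 2.86 and the spread median 3.43. The 22 stacked clusters of class C2 had a median of 2.81 with an interval of 1.03 to 4.52. Spread clusters lay in loci of several clusters in 92.7% of cases and stacked ones in 5.13%. Since counts can include reads from outside a cluster, the split can follow in part from the density of the locus. In the untagged list, 404 of 636 clusters of at least 20 reads were stacked (63.5%), against 27.4% in the tagged list, and the pooled order was the reverse, with median log2 ratios of 0.59 (0.5 to 0.67) for spread and 0.93 (0.87 to 1) for stacked clusters. By read total, these untagged-list medians for spread and stacked clusters were 1.07 and 1.42 at 20 to 29 reads, 0.88 and 1.13 at 30 to 49, and 0.63 and 0.77 at 50 to 99. At 100 or more reads, which 74 of the 127 spread clusters had, they were 0.44 (0.4 to 0.49) and 0.45 (0.41 to 0.53). The intervals of spread and stacked clusters overlapped at 20 to 29 reads (1 to 1.46 and 1.26 to 1.52) and at 50 to 99 (0.54 to 0.78 and 0.67 to 0.9). Within class B the medians were 0.76 (0.66 to 0.87) and 0.94 (0.88 to 1). Within class C2 they were 0.48 (0.41 to 0.56) and 0.65. The latter came from 8 stacked clusters and had an interval of 0.24 to 1.62, so the order within class C2 is not settled. Region B clusters made up 89.9% of the untagged list and 49.1% of the tagged list, and those named region C2 made up 9.61% and 42%. At 20 reads or more, the median share of reads at the highest position was 91.3% in class B and 32.7% in class C2 of the tagged list, and 95.7% and 30% in the untagged list.

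**Figure D4:**
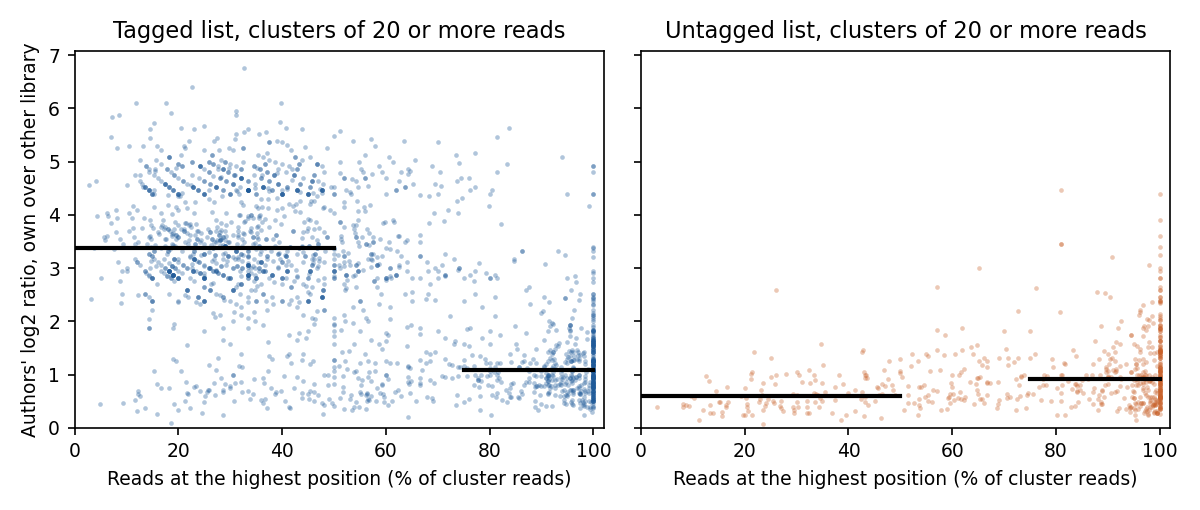
Authors' log2 ratio of own to other reads (y axis) against the listed count at the highest position as a percent of the listed read count (x axis). Shown are clusters of at least 20 reads, 1995 in the tagged list (left) and 636 in the untagged list (right). Each point is a cluster; black lines are medians of spread and stacked clusters, 3.37 and 1.1 on the left and 0.59 and 0.93 on the right.

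The 2 lists shared 0 bases on either strand, and since each was selected against the other library, the same cluster could hardly enter both. Within 1000 nt on the same strand, 47 untagged-list clusters (4.14%) had a tagged-list cluster, in 17 loci. The one with the most tagged-list clusters was the chrM locus, with 34 tagged-list and 5 untagged-list clusters. The next, on chromosome 17, plus strand, positions 39982034 to 39985445, had 6 tagged-list clusters with a median log2 ratio of 0.49 and 24 untagged-list clusters with a median of 0.41. On chromosome 10, minus strand, positions 83989498 to 83990478 held 6 tagged-list clusters with a median of 2.7 and 1 untagged-list cluster at 0.74.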

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

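Of 57 alternatives, 32 stayed within the limits set for them (1.5 times a count, or the 95% interval of a share or median) and 25 moved beyond them. Some of the 32 could not move by construction. The length limit removed no untagged-list cluster, all untagged-list clusters passed the depth-aware test, and a stricter overlap rule cannot lower a count of 0. For the 25 that moved, the cause was not tested except where fewer clusters entered by construction. No paired analysis was possible because each group has 1 library. Taking the 50% of clusters with the lower p, ties kept, left 6098 tagged-list and 567 untagged-list clusters in 2435 and 538 loci; medians of the log2 ratio became 3.17 and 1.28, shares with 0 reads in the other library 64.1% and 6.7%, and 75.3% of tagged-list clusters had a neighbour within 1000 nt. Under the depth-aware test, added after seeing the data, 8634 tagged-list clusters remained, with a median of 3, 63% with 0 other reads and 73.6% with a neighbour; all 1134 untagged-list clusters passed, as the expected share is lower for that library. Without class B, 1728 tagged-list and 75 untagged-list loci were left, and 87.6% and 48.7% of clusters had a neighbour. The chromosome 17 locus was not left out of that untagged-list share. The stacked tagged-list clusters outside class B had a median of 2.86, but class B held 518 of the 546, so few entered. Without the chromosome 17 locus of 22 untagged-list clusters, 3.87% of untagged-list clusters had a neighbour. Without the wider chromosome 17 locus of both lists, untagged-list clusters near a tagged-list cluster had medians of 82 reads and 0.59. Strand agreement, leaving out class B or either chromosome 17 locus, and limits on reads were likewise chosen after seeing the data. Strand agreement within 100000 nt was 94.2% and 63.3%. These shares include the closer pairs: 6955 of 8327 tagged-list and 48 of 120 untagged-list pairs lay within 1000 nt. At 50 or more reads, spread and stacked medians were 3.75 and 0.795. Counting clusters within 50 nt as shared gave 11 in place of 0. Merging clusters within 50 nt left 7902 in the tagged list, close to its limit, and 1107 in the untagged list. Not run, for lack of an mm9 annotation or sequence here: the alternatives for genomic features, genes, gene lists, sequence and miRNA seeds. Low counts limit the tagged list, since 2714 clusters rest on 5 reads against 0.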

Other observations

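The tests on copies made in 1 library and on the depth factor were chosen only after the result was seen. A small class named region C1 by the authors, with 140 tagged-list clusters, had a median of 6 reads and a median of 16.7% of reads at the highest position. For a cluster of 6 reads, 16.7% is 1 read, the lowest share possible, so this median follows from the low counts. Tagged-list clusters in loci of several clusters passed the binomial test with the depth factor more often (78.4%) than single clusters did (62.5%). The cluster with the most reads in the tagged list, on chromosome 3, plus strand, in the locus from 5860685 to 5860762, had 4343 tagged reads and a log2 ratio of 0.09, and the same locus held an untagged-list cluster with 1322 reads and a log2 ratio of 0.5.

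In the tagged list, clusters called stacked had lower ratios than clusters called spread. The split itself can follow in part from the density of the locus, through reads from outside a cluster, which was not tested. Read depth of the clusters did not account for the lower ratios up to 99 reads. Over 4 ranges of the cluster's own read total, the smallest difference of median log2 ratios was 1.64, at 20 to 29 reads. At 100 or more reads the difference was 2.83, but the intervals of spread (0.75 to 4.06) and stacked clusters (0.51 to 0.75) met. Copies of single molecules made in 1 library alone stay open: 97.1% of the stacked clusters had reads in the untagged library, but a low ratio at 20 or more reads already requires such reads, so this decides nothing. The authors' cluster class stays open too: the difference was 1.8 in class B but 0.625 in class C2, where 22 stacked clusters had a median with an interval of 1.03 to 4.52. A candidate explanation that was not tested is that stacked positions are background shared by both libraries and spread clusters are bound RNA, which would need replicates and sequence.

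The scaled untagged reads at tagged-list clusters took no value of 1, 4 or 7. Over values of 1 to 60, 100% of those at 1690 held-out clusters were rounded multiples of a factor of 1.512 fitted on 1691 other clusters. Multiplication by 1 depth factor and rounding would give this. In the untagged list 59.3% of 776 values were such multiples. These values are no unscaled control, since the tagged reads there were taken as scaled by the inverse of the factor. The share expected of arbitrary whole numbers was not computed. The held-out fit did not test the factor used, 1.501, which was narrowed with the higher values. In the authors' test at an even split, 5 reads against 0 give a p of 0.0313 (exact, one-sided), and with the depth factor as the expected odds they give 0.0779, and 3036 tagged-list clusters, 2714 of them at 5 reads against 0, depend on the choice between these tests. No biological explanation was tested for this pattern.

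Clusters of both lists lay within 1000 nt of each other on 1 strand at 17 loci. Small differences at heavily read loci may account for this in part, but the larger of the median log2 ratios of these clusters was 1.33, between the values set beforehand for and against it, so this stays open. That test used ratios and not read counts, and the 52 tagged-list clusters near an untagged-list cluster had a median of 28 reads. The 47 untagged-list clusters had a median of 1322 reads and a median log2 ratio of 0.48, but 23 of them were among the 24 untagged-list clusters of the chromosome 17 locus of both lists (39982034 to 39985445), and without that locus, an alternative chosen after seeing the data, these medians were 82 and 0.59, while the tagged-list median log2 ratio was 1.68. No biological explanation was tested for this pattern.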
